A study of Halobacterium salinarum NRC-1 with 6 samples.

How the data were processed

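RNA of Halobacterium salinarum NRC-1 was compared between copper-treated cultures and an untreated control on 2-colour arrays. Per the labels, mid-log cultures were exposed for 5 h to 0.7, 0.85 or 1.0 mM copper sulfate, and total RNA was extracted, checked and labelled with Alexa 532 or Alexa 647. Each copper sample was hybridised on 2 arrays with the dyes exchanged, so the labels give 3 samples on 6 arrays. The 2 arrays of a dose were counted as 1 replicate. The steps the authors took between the scans and the table, such as background correction and normalization, are not given in the sources used here.

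The deposited table holds 1 value per spot and array, 10752 spots on each, read here as a log10 ratio of the channels. The base is not stated. Adjacent repeat spots on an array differed by an SD between 0.0535 and 0.0641 in the deposited unit, which is a spot error of 9.11% to 11.0% if the base is 10 and of 2.66% to 3.19% if it is 2. Base 10 was taken, and all ratios were converted to log2. The tests do not depend on the base, but each fold, log2 ratio and size threshold does. The column medians as deposited were 0.0406, 0.102, 0.103, 0.160, 0.105 and 0.150, in order of dose with copper in the 532 channel first, so the arrays were not centred on 0. Signal and background per channel were not analysed here.

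Values of exactly 0 made up 14.0% of spots with copper in the 532 channel at 0.7 mM, 6.10% on its dye-exchanged partner and 0.0186% on the first array at 1.0 mM. They were treated as missing, because the spots that were 0 on the first array had a median log2 value of 1.45 on the 4 later arrays, against 0.29 for other spots. Each probe had 4 spots, an adjacent pair and a second adjacent pair 5376 spots further on, a layout checked on all 133 named genes. The spots of a probe were averaged within an array. This gave 2688 probes, and 2687 had a value in each sample.

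The platform annotation given names 133 genes, each by 1 symbol, 0 probes carried several symbols, and 2555 probes are unnamed here. The gene table provided belongs to another strain of the species (assembly ASM479960v1). All 133 symbols occur in it and 0 of the numeric gene identifiers do, so it was used for names and for which genes lie next to each other, and no coordinates are printed.

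The direction of the values was examined in each pair of dye-exchanged arrays. A rule set before the data were examined took a correlation above 0 between the 2 arrays of a dose as a sign that the values were already turned to copper over control. The correlations were 0.735, 0.905 and 0.892 across probes. That rule was not followed, a choice made after the data were seen. The difference between the 2 pairs of spots of a probe was assumed to follow slide position and dyes, not copper. That assumption was not tested. The difference kept its sign under the dye exchange, with correlations of 0.409, 0.830 and 0.771. The values were therefore read as following the dyes, with a large component common to both orientations. The copper ratio of a probe was computed as the difference of the 2 orientations divided by 2, and its dye component as their sum divided by 2. Over probes the SD of the dye component was 0.46, 0.55 and 0.55 at the 3 doses and that of the copper ratio 0.20, 0.14 and 0.13. The copper ratio still correlated with the dye component, at -0.557, -0.456 and -0.133. Which dye is the numerator is not stated. Copper over control was assumed, because the labels' descriptions name the first channel before the second. That order does not settle which channel is the numerator.

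The mean ratio over the 3 samples was tested against 0 with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all probes. The limma tests were two-sided with a threshold of 0.05. The mean has 2 residual degrees of freedom, to which moderation added a prior of 6.26. The control RNA was the common reference on all arrays, so the test leaves out the control's own spread, which was simulated 100 times as a control that varies like the samples. The dose trend was fitted with limma on dose in mM, with 1 residual degree of freedom. At each dose, probes with a log2 ratio of at least 1 in size in both orientations were counted without a test. Gene lists, 27 in number, were fixed before the data were examined, matched by symbol and tested from 3 measured genes upward with camera at a preset correlation of 0.01, with adjustment over the lists.

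The rule for named genes was fixed in advance. It takes the 12 genes with the highest and the 12 with the lowest mean ratio among those past the threshold with the same sign on all 6 arrays, filled up with genes of 1 sign that did not pass. It adds up to 4 leading members of each list that passes camera, a fixed set of copper and stress genes of which dnaK was measured, and the 3 genes with the lowest trend p in each direction. Because the dye component outweighs the copper ratio, only 2 named genes past the threshold had 1 sign on all 6 arrays. The rule was therefore applied after each probe's mean dye component was subtracted, which 22 passed, and this change was made after the data were seen. The subtraction gives both orientations of a probe the same mean, so 1 sign on all 6 arrays is then no check of the dye exchange.

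The fits were tested on simulated data with 2687 probes. For the mean over doses, 71.6% of added log2 ratios of 0.25 were recovered and 100% of those of 0.5 and of 1. There were 17 false calls in 198. That count sets no false-call rate for the 348 calls in the data. Simulated unchanged samples that share a variable control gave a median of 321 calls. For the dose trend, 8.96% of slopes of 1 log2 unit per mM were recovered, 82.1% of slopes of 2 and 100% of slopes of 4. There were 27 false calls in 154. In each fit the false calls were a larger share of all calls than the adjustment threshold allows.

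Alternatives fixed in advance were centring of each array, centring with scaling, medians of spots, probes with every spot, each dye orientation alone, each sample left out, 6-array fits, other moderation, other thresholds, and other list tests and correlations. The arrays not turned, as the rule set in advance would have left them, became an alternative after the data were seen. Added after the data were seen were zeros kept, each pair of spots alone, removal of each array's smooth dependence on the dye component by loess with a span of 0.4, adjustment over named genes alone, values read as log2, and lists set against named genes alone. Figures were drawn with matplotlib 3.10.9.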

Results

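RNA abundance was measured in Halobacterium salinarum NRC-1, an archaeon that grows in near-saturated brine, after 5 h in copper sulfate. Mid-log cultures received 0.7, 0.85 or 1.0 mM of the salt, and RNA from each was hybridised against RNA of an untreated control on 2-colour arrays. Each of the 3 copper samples was run on 2 arrays with the dyes exchanged, so the 6 arrays give n = 3. The 3 samples had different copper doses, so the spread between them holds dose differences besides technical ones. The p-values measure only that spread, and a dose effect counts as spread in the test of the mean. The labels do not say whether the samples were grown from separate starting cultures. There was 1 sample per dose and no control sample measured apart from the shared reference. Each array held 10752 spots for 2688 probes, of which 2687 could be tested and 133 carried a gene name. The number of arrays limits the precision.

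The first comparison asks which genes had RNA levels in copper that differed from the control, averaged over the 3 doses. Ratios are log2 of copper over control, a direction that was assumed and is not stated. If the deposited values run the other way, all signs of the copper ratios below turn together. The ratios also rest on turning the arrays by their dyes, a choice made after the data were seen. If the deposited values were already turned, the ratios given below would not be copper ratios, and more than their signs would change. The highest named gene was carB, the large subunit of carbamoyl phosphate synthase, which feeds pyrimidine and arginine synthesis. It rose by 0.40 ± 0.03 (SD, n = 3), a 1.32-fold change, with 0.37, 0.38 and 0.43 at the 3 doses in rising order. Next was purL, an enzyme of purine synthesis, which rose by 0.38 ± 0.07. The phosphate uptake regulator phoU rose by 0.25 ± 0.05, and arcA, the arginine deiminase of arginine fermentation, by 0.22 ± 0.10. Their limma p-values after Benjamini-Hochberg adjustment were 0.00435 for carB, 0.00665 for purL, 0.0245 for phoU and 0.0371 for arcA. With arrays not turned, the rule set in advance, they were at -0.11, -0.075, -0.32 and -0.31. The limma adjusted p-values were then 0.0812, 0.279, 0.00169 and 0.00399.

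Among the named genes 20 were lower in copper, all by small amounts. The largest fall was in hutU, the urocanate hydratase of histidine breakdown, at -0.32 ± 0.18 (SD, n = 3). The formiminoglutamase hutG of the same pathway was at -0.24 ± 0.15. The deoxyribose-phosphate aldolase deoC was at -0.29 ± 0.17 and the cyclohydrolase mch of one-carbon metabolism at -0.28 ± 0.04. The purine enzyme purB was at -0.27 ± 0.15, in contrast to purL. The mutase subunit mamA was at -0.26 ± 0.18, the tRNA nucleotidyltransferase cca at -0.25 ± 0.03 and the mismatch repair gene mutL at -0.24 ± 0.05. The transducer gene htr4 was at -0.24 ± 0.07, the histidyl-tRNA synthetase hisS at -0.23 ± 0.03, the menaquinone synthesis gene menD at -0.22 ± 0.03 and the glycolytic enzyme tpiA at -0.22 ± 0.03. Adjusted limma p-values for these 12 genes lay between 0.0169 for mch and 0.0484 for mamA. Past the threshold, too, were gdhA2, thrS, nadA, radB, dcd, map, mvk and thiL, which the naming rule does not pick and which are named here after their values were seen. Of the 12 genes, hutU, hutG, deoC and mamA lacked some spots. With zeros kept none of these passed, at limma adjusted p-values of 0.0528, 0.0692, 0.0518 and 0.0878. With arrays not turned, the rule set in advance, hutU was at 1.20.

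**Figure D1:**
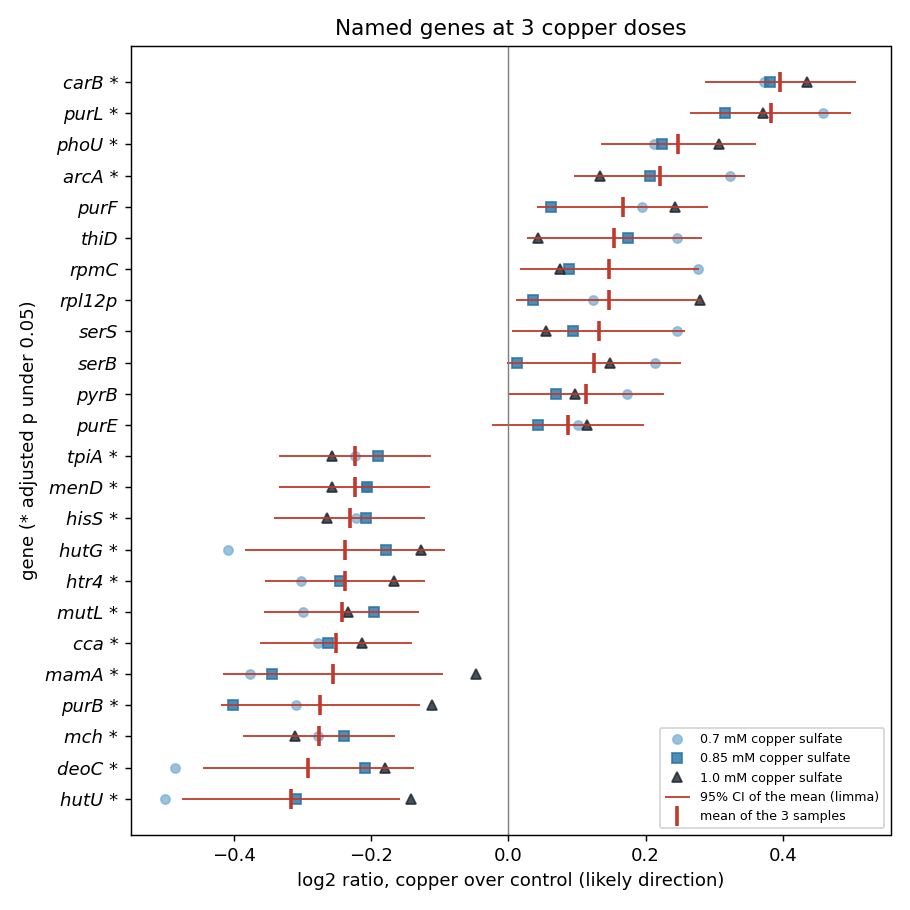
Log2 ratio of copper over control (horizontal axis) for 24 named genes (vertical axis), with a point per dose. The axis calls the direction likely, but it was assumed. The mean of the 3 samples is a red tick and its 95% limma confidence interval a red line. carB and purL stand highest at 0.40 and 0.38, hutU lowest at -0.32, and genes without an asterisk did not pass adjusted p 0.05; after centring of each array none of the lower genes passed.

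Of all 2687 probes, 348 passed adjusted p 0.05 in limma, 63 higher and 285 lower in copper. Of the 133 named genes 24 passed, 4 higher and 20 lower. When the adjustment ran over the named genes alone, 28 passed, 4 higher and 24 lower. The 8 next highest named genes with 1 sign on all 6 arrays, after the dye component was subtracted, did not pass. They were purF at 0.17, thiD, rpmC and rpl12p each at 0.15, serS and serB each at 0.13, pyrB at 0.11 and purE at 0.09. With the dye component left in, each of these 8 differed in sign between arrays. The chaperone gene dnaK was at -0.03 ± 0.07, with a limma adjusted p of 0.702, and at 0.06 after centring of each array. The extremes lay at probes with no gene name here. Spot 1849 had a mean ratio of 1.08 and spot 4795 of 0.81, and spot 5053 had -0.72 and spot 5243 -0.59.

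The split between higher and lower genes depended on how the arrays were scaled. Centring each array on its median, which raised all ratios by 0.09 on average, gave 115 higher and 29 lower probes. With that scaling 7 named genes were higher, carB, purL, phoU and arcA among them, and 0 were lower, with 43 named genes at an unadjusted limma p under 0.05. When each array's smooth dependence on the dye component was removed, a choice made after the data were seen, 66 probes were higher and 40 lower. Then carB, purL and phoU were the higher named genes and hisS, at -0.21 with a limma adjusted p of 0.0340, was the lower one. With the same removal arcA was at 0.19 with a limma adjusted p of 0.0597. Centring with scaling ended the calls of phoU, at 0.22 with a limma adjusted p of 0.0700, and of arcA, at 0.20 with 0.108. A fit without moderation called 0 probes, with 501 at an unadjusted p under 0.05, and leaving out the 0.85 mM sample left 4 calls in limma, with carB and purL each at an adjusted p of 0.157. The test leaves out the control's own spread, and simulated unchanged samples sharing 1 equally variable control gave a median of 321 calls, with 147 to 461 over 100 simulations.

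**Figure D2:**
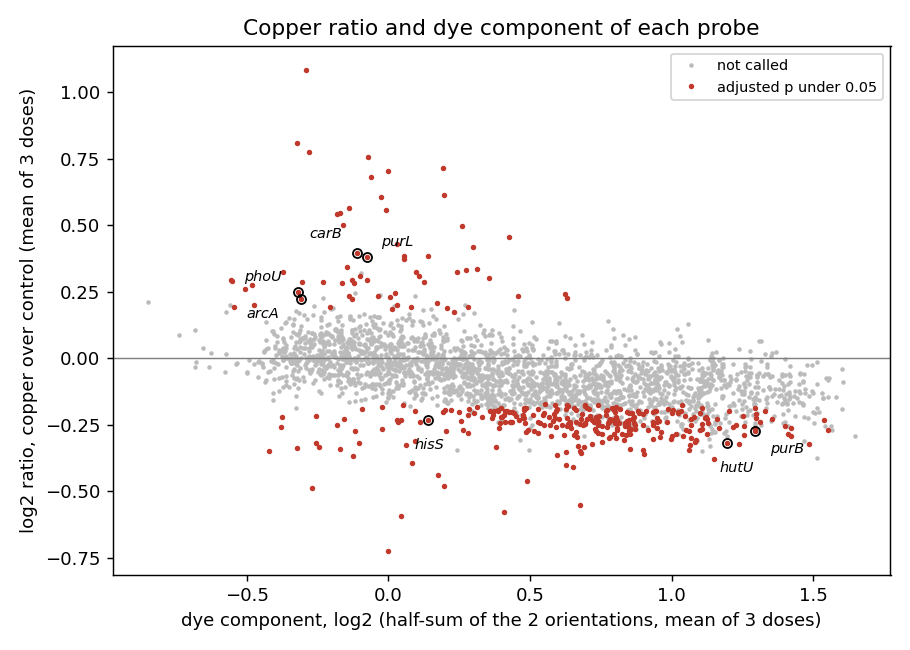
Mean log2 ratio of copper over control (vertical axis, assumed direction) against the dye component of each of 2687 probes (horizontal axis, log2). The 348 probes past adjusted p 0.05 are in red and 7 named genes are circled. Lower calls had a median dye component of 0.72 and uncalled probes one of 0.39; carB, purL, phoU and arcA lie at negative dye components.

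The gene lists ask which known functions moved together. Purine and pyrimidine synthesis was the 1 list of 8 tested that passed limma's camera, upward against all probes. Of its 10 measured genes purL rose, purB fell and 8 did not pass. Adjusted over the list alone, 2 rose and 1 fell. After purL the highest members were purF at 0.17, pyrB at 0.11 and purE at 0.09, and the mean of the 10 was 0.04. The adjusted camera p was 0.0188, and the call was lost at adjusted p = 0.802 with an estimated correlation. limma's fry, which asks whether the members move one way, gave an adjusted p of 0.273. The camera call was also lost after centring, with an adjusted p of 0.0671, and with the dye dependence removed, with 0.178.

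The other 7 tested lists did not pass camera on the values as deposited. Of 11 measured genes for the archaellum, chemotaxis and transducers, htr4 fell, 10 did not pass and 0 rose. Adjusted over the list alone 0 rose and 2 fell. This list passed camera downward after centring and scaling, at an adjusted p of 0.0158, and with the dye dependence removed, at 0.0351. Both calls were lost, at adjusted p = 0.805 and adjusted p = 0.918 with an estimated correlation. Of 4 DNA repair genes, mutL and radB fell and 2 did not pass, also when adjusted over the list alone. Of 12 aminoacyl-tRNA synthetases, hisS and thrS fell and 10 did not pass, with the same 2 counted as lower when adjusted over the list alone. Of 6 chaperone and protease genes 0 rose and 0 fell, over all probes and adjusted over the list alone, with 0 at an unadjusted limma p under 0.05, and dnaJ was at 0.00 and psmB at 0.02. The symbol panB, counted in that list at -0.10, is also used for an enzyme of coenzyme A synthesis. Of 4 retinal protein genes 0 passed over all probes, and bat, a regulator of the opsin genes, fell when adjusted over the list alone. Of 6 tricarboxylic acid cycle genes and 4 cobalamin genes 0 passed, in either way of adjusting, and 0 had an unadjusted limma p under 0.05. The adjusted camera p-values of these 7 lists lay between 0.275 for cobalamin and 0.950 for the synthetases. With fry the chemotaxis list, the DNA repair list and the synthetases passed, at adjusted p-values of 0.0124, 0.0178 and 0.0444, a test against no change on arrays that are not centred. Their members' means were -0.09, -0.10 and -0.06 as deposited and 0.0014, -0.01 and 0.02 after centring.

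A further 7 lists had 1 or 2 measured genes and were not tested. In the phosphate uptake list phoU was the single gene, and it rose. In arginine fermentation arcA rose and arcC was at 0.01. The thiol and oxidative stress genes msrA, a methionine sulfoxide reductase, and dpsA, a DNA-protecting ferritin-like protein, were at -0.11 and -0.14. Neither passed over all probes in limma, and both were lower when adjusted over the list alone. The ribosomal protein gene rpl12p was counted as higher when adjusted over its list alone. For 12 lists, which include metal efflux, metal uptake, iron-sulfur cluster assembly, gas vesicles and the copper genes remembered from a paper on these arrays, no member carried a name, and they were not analysed here.

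The second comparison asks whether RNA levels followed the copper dose from 0.7 to 1.0 mM. The strongest named trend was in gatC, a subunit of a tRNA-dependent amidotransferase, at 2.51 log2 units per mM. Its ratio was -0.73, -0.23 and 0.02 at the 3 doses in rising order. The histidine breakdown gene hutI followed at 1.77 per mM and the transducer gene htr18 at 1.25. In the same order of doses hutI was at -0.55, -0.18 and -0.02, and htr18 at -0.44, -0.21 and -0.07. Like gatC, both lay furthest from control at 0.7 mM and nearest to it at 1.0 mM. In the opposite direction were speB, an agmatinase of polyamine synthesis, at -1.67 per mM and csg, the surface layer glycoprotein, at -1.27. The ratios of csg were 0.32, -0.0053 and -0.06, furthest from control at 0.7 mM. Those of speB were 0.15, 0.03 and -0.35, furthest at 1.0 mM. Adjusted limma p-values were 3.7e-07 for gatC, 7.34e-04 for hutI, 0.0360 for htr18, 0.00158 for speB and 0.0320 for csg. The proteasome-activating gene pan1 was at -1.08 per mM with a limma adjusted p of 0.0854.

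The trend passed in 201 probes, 153 upward and 48 downward. Of the 133 named genes 8 passed, 6 upward and 2 downward, the others being trpB, trpC and hutU, named here after their values were seen. When adjusted over the named genes alone, gatC, hutI and speB remained. Across the lists, the ratio of htr18 rose with dose, from below control, among the 11 chemotaxis and transducer genes, also when adjusted over the list alone. Among the 6 chaperone and protease genes pan1 fell with dose when adjusted over the list alone. Limma's camera called 0 lists for the trend, 0 at an unadjusted p under 0.05, with the lowest adjusted p at 0.663. The trend has 1 residual degree of freedom, and limma gave every probe the same standard error of 0.41 log2 units per mM, as its estimated prior degrees of freedom were infinite. The trend p-values therefore rank the size of the slope and do not measure a gene's own scatter. With the dye dependence removed 97 probes passed, 46 upward and 51 downward. Among them gatC was at 1.78, speB at -1.85 and pan1 at -1.73 per mM, at limma adjusted p-values of 0.00114, 6.51e-04 and 0.00183. In the same setting hutI, htr18 and csg were at 1.26, 1.03 and -0.70 per mM, at limma adjusted p-values of 0.0502, 0.140 and 0.410.

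The third comparison asks how many probes moved far at each dose. No test exists for 1 sample per dose. A log2 ratio of 1 or more in size in both dye orientations was reached by 0 probes at each of the 3 doses. The highest ratio was 1.39 at 0.7 mM, 0.88 at 0.85 mM and 0.98 at 1.0 mM. The lowest ratios were -0.89, -0.69 and -0.84. At 0.7 mM hutU was at -0.50, deoC at -0.49, purL at 0.46 and carB at 0.37. At 1.0 mM carB was at 0.43, purL at 0.37, phoU at 0.31, mch at -0.31 and hutU at -0.14.

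The fourth comparison asks how far the doses resemble each other across probes. Across 2687 probes Pearson's r was 0.65 between 0.7 and 0.85 mM, 0.40 between 0.7 and 1.0 mM and 0.54 between 0.85 and 1.0 mM. Probes are not independent replicates. Unchanged samples that share 1 control gave a simulated r of 0.50 for each pair. The simulation gave the control and each sample the same spread, which fixes r near that value. The control's spread was not measured, and the SD of the copper ratio was 0.20, 0.14 and 0.13 at the 3 doses. The covariances were 0.0182, 0.0108 and 0.00974 in the same order, against simulated values of 0.0133, 0.0134 and 0.0133. For both pairs with 1.0 mM the covariance was below the simulated one, so a shared control with the assumed spread could give that much. The control cannot be split here. Among named genes, the SD over the 3 doses was 0.03 for carB, 0.38 for gatC and 0.27 for hutI.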

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

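The test of missing spots was fixed before its result was seen; the tests of dye bias, of the array offset, of the pairs of spots and of the shared control, given here, were chosen after the results were seen. A limma trend test found effects that differ between doses in 201 probes. Among named genes the slopes were 2.51 log2 units per mM for gatC, 1.77 for hutI, 1.25 for htr18, -1.67 for speB and -1.27 for csg.

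The dose trend calls could come from the arrays. Of the 201 calls 75 stayed past the threshold when the dye dependence was removed, below the bound of 1 in 2. Of the calls 70.1% had at least 1 missing spot, against 27.3% of other probes, and among probes with every spot 27 trends were upward and 43 downward, against 153 and 48 overall; the second pair of spots gave no value at 0.7 mM for gatC, hutI, htr18 and speB. Either pair of spots alone gave 0 trend calls in limma, with 282 and 288 probes at an unadjusted p under 0.05, but the slopes with the first pair were 2.12 for gatC, 1.25 for hutI, 0.92 for htr18, -1.24 for speB and -1.19 for csg, and csg was at -1.34 with the second pair. Both technical readings stay open beside a response to copper dose, which 1 sample per dose cannot separate from a difference between arrays.

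More probes lay below the control than above it, 285 against 63. Centring each array left 29 lower calls, but it shifts all ratios upward by 0.09 on average, so this fall decides nothing about an offset between arrays, which stays open. The lower calls had a dye component 0.33 higher than uncalled probes, 0.72 against 0.39, which is consistent with a dye bias, and removing the dye dependence, which also centres each array, left 40. The first pair of spots alone gave 443 lower calls and the second 58. A general fall of RNA levels in copper was not tested apart from these.

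The genes carB, purL, phoU and arcA lay above the control at all 3 doses. In the order given they were at 0.45, 0.37, 0.29 and 0.20 in the first pair of spots and at 0.34, 0.40, 0.20 and 0.24 in the second. Their mean ratio was 0.30 in the lower of the 2 pairs and 0.33 in the other. This argues against a defect in 1 pair of spots as the whole cause, though the genes were picked on both pairs together. In the second pair alone phoU and arcA did not pass, at limma adjusted p-values of 0.0890 and 0.0558. Removing the dye dependence, which also centres each array, left a mean of 0.29 ± 0.03 (SD over samples), against 0.31 as deposited. Centring alone put carB, purL, phoU and arcA at 0.48, 0.47, 0.34 and 0.31, and the removal at 0.38, 0.37, 0.22 and 0.19. This argues against a bias that follows the dye component as the whole cause, and leaves it open as a part. The bound for this test was changed after its result was seen. With the removal arcA, at 0.22 ± 0.10 as deposited and then at 0.19 ± 0.06, no longer passed, at a limma adjusted p of 0.0597. A deviation of the single control RNA cannot be told apart from a copper effect, because simulated unchanged samples with 1 shared control gave a median of 321 calls. A response of these genes to copper stays open beside it.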

How the results depend on the processing

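Turning the arrays by their dyes was itself chosen after the data were seen, and arrays not turned is the rule set in advance. Also chosen after the data were seen were the settings with zeros kept, 1 pair of spots alone, the dye dependence removed, adjustment over named genes alone, values read as log2 and lists set against named genes alone. The others were planned. Except where a value or the setting's construction shows it, the cause was not tested. Against 348 calls for the mean over doses, limma gave 144 after centring, 77 after centring and scaling, 212 with zeros kept, 502 with the first pair of spots, 59 higher and 443 lower, 103 with the second, 45 higher and 58 lower, and 106 with the dye dependence removed. It gave 30 at adjusted p under 0.01, 759 under 0.1, 1 with a mean log2 ratio of at least 1 as well, and 0 without moderation. Leaving out 1 sample gave 4 to 412 calls, 4 without 0.85 mM and 184 without 1.0 mM, where 2 samples leave 1 residual degree of freedom. The gene carB stayed above control except with arrays not turned, with ratios from 0.28 to 0.51 otherwise, and lost its call without 0.85 mM. The gene phoU lost its call after centring and scaling, at an adjusted limma p of 0.0700, without 0.85 mM at 0.253, without 1.0 mM at 0.0649 and with the second pair of spots at 0.0890. Settings where arcA lost its call include centring and scaling, at an adjusted limma p of 0.108, and medians of spots at 0.0501. Its call was also lost with zeros kept at 0.0518 and with the second pair of spots at 0.0558. With arrays not turned there were 2204 calls, 1808 higher and 396 lower. With copper in the 532 channel alone there were 1928, 1643 higher and 285 lower. The 647 channel alone gave 2144, 369 higher and 1775 lower. On the reading used here these 3 settings keep the dye component by construction, whereas on the rule set in advance arrays not turned give the copper ratio. Against 201 trend calls there were 111 after centring and scaling, 70 among probes with every spot, 27 upward and 43 downward, 97 with the dye dependence removed and 96 in the 6-array fit. There were 0 trend calls with either pair of spots alone, with arrays not turned, and with the 647 channel alone, in limma, with 282, 288, 160 and 311 at an unadjusted p under 0.05. Against 1 list past camera, 0 passed after centring, among probes with every spot, with the second pair of spots, with an estimated correlation and with ranks. 4 lists passed with the 532 channel alone and with arrays not turned, 5 with the 647 channel alone and 3 with fry, and after centring and scaling and with the dye dependence removed the 1 list was the chemotaxis list, at 0.0158 and 0.0351, in place of the nucleotide list, and both calls were lost at adjusted p = 0.805 and adjusted p = 0.918 with an estimated correlation. Leaving out 1 sample gave 0 to 1, with 0 without 0.7 mM and without 1.0 mM. Against 0 probes per dose, 11, 6 and 6 reached 0.58 in both orientations at the 3 doses in rising order, 2 reached a mean of 1 at 0.7 mM, 1 reached 1 at 0.85 mM with the second pair of spots, and 1 at 0.7 mM with the dye dependence removed.

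Agreement between doses moved too. Between 0.7 and 0.85 mM r was 0.49 after centring and scaling, 0.54 with the second pair of spots, 0.53 with the dye dependence removed and 0.76 among 1284 probes whose orientations lie within 1. Between 0.7 and 1.0 mM it was 0.54 among probes with every spot and 0.62 within 1. Between 0.85 and 1.0 mM it was 0.65 with every spot, 0.73 within 1 and 0.43 as Spearman's rho. In the order of these pairs it was 0.84, 0.87 and 0.95 with the 532 channel, 0.89, 0.87 and 0.97 with the 647 channel, and 0.91, 0.92 and 0.98 with arrays not turned.

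Of values past the threshold before or after, signs turned only with 1 channel alone and with arrays not turned. On the reading used here these settings keep the dye component. On the rule set in advance, the values with arrays not turned are the copper ratios themselves. With the 532 channel alone phoU was at -0.071, arcA at -0.087, pyrB at -0.27, hutU at 0.88, deoC at 0.71, mch at 0.21, purB at 1.02, mamA at 1.14, cca at 0.36, mutL at 0.53, htr4 at 0.17, hutG at 0.71, menD at 0.14 and tpiA at 0.25. The camera direction turned for the chaperones, the tricarboxylic acid cycle, cobalamin and the nucleotide list, at adjusted p-values of 0.0458, 0.00389, 0.00204 and 0.328. With the 647 channel alone dnaK was at 0.18 and the chemotaxis list turned at an adjusted p of 0.0144. With arrays not turned carB was at -0.11, purL at -0.075, phoU at -0.32, arcA at -0.31, thiD at -0.24, pyrB at -0.38, purE at -0.24, hutU at 1.20, deoC at 1.00, mch at 0.49, purB at 1.30, mamA at 1.40, cca at 0.61, mutL at 0.78, htr4 at 0.41, hutG at 0.95, hisS at 0.14, menD at 0.37 and tpiA at 0.48. The trends of gatC, hutI and speB were then -0.037, -0.12 and 1.44 per mM. The chaperone, tricarboxylic acid cycle, cobalamin and nucleotide lists turned, at adjusted p-values of 0.0306, 0.00410, 0.00136 and 0.0599.

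Leaving out transposases was not run, as none carries a name here, and the count in both orientations has no value for 1 channel alone. Dose by rank gives the same trend, since the doses are evenly spaced. No paired analysis was possible because each dose has 1 sample. Signal over background was not analysed here, so its limit on dim probes is unknown.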

Other observations

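The tests given here were chosen after the results were seen. Histidine breakdown and tryptophan synthesis were not among the fixed lists. The histidine breakdown genes hutU, hutI and hutG had mean ratios of -0.32, -0.25 and -0.24, and their ratios at 0.7 mM were -0.50, -0.55 and -0.41. Of these, hutI did not pass the limma test of the mean, with an adjusted p of 0.0896. The tryptophan synthesis genes trpC and trpB were at -0.25 and -0.22 with limma adjusted p-values of 0.0559 and 0.0826. With the dye dependence removed, hutU, hutI and hutG were at -0.18, -0.12 and -0.11, with limma adjusted p-values of 0.105, 0.366 and 0.292, and trpC and trpB at -0.12 and -0.08. The dye components of hutU, hutI and hutG were 1.20, 1.14 and 0.95. The 2 subunits of carbamoyl phosphate synthase stood apart, with carB at 0.40 and carA at 0.08, the latter with a limma adjusted p of 0.266; their difference was not tested.

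Genes next to each other on the chromosome may change together. Over 28 pairs of named genes that are neighbours or 1 gene apart in the annotation of the other strain, the mean absolute difference in ratio was 0.11, against 0.14 for permuted genes. The permutation p was 0.0488 one-sided, for a smaller difference, and 0.110 two-sided, with 100000 permutations. With the dye dependence removed the difference was 0.09 against 0.11, and the p-values were 0.143 and 0.289. The hypothesis stays open. Some neighbours also have close spot numbers, such as hutI at 3059 and hutU at 3067. Others do not, such as gatC at 2881 and gatA at 4649. A local effect on the slide was not tested for these pairs. The order of genes in strain NRC-1 was not used here.

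Across the 3 samples 18 probes had a mean ratio of 0.5 or more in size, and the simulations of unchanged samples with a shared control gave a median of 8 and at most 15. The largest mean ratio was 1.08 in size, and the largest in any of the simulations was 1.80.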
